A study of Drosophila melanogaster with 3 samples.

How the data were processed

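Peak lists from 3 biological replicates of anti-GFP ChIP-seq on whole embryos (0 to 16 hours) expressing CG2712 with a GFP tag were used, with the list called on the replicates together and the IDR list. The replicates form 1 group and the labels number them as biological replicates, so the spread between them covers separate samples of 1 kind. Per the labels the reads were placed on build dm6, and the labels give a size range of 200 to 800, with no unit. Per the text that accompanies the deposited lists, the peaks of each replicate were called on that replicate's alignments against 1 control file, the pooled list on the alignments of all 3 replicates, and the IDR list from these. The peak caller, its settings, the aligner and the IDR threshold were not given in the sources used here.

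The deposited lists follow the narrowPeak layout, in which the authors' signal value is the enrichment that the caller gave a peak. The deposited q value is given as −log10 q and reached 1 highest value in each list (4.34 in the IDR list, where all 9789 peaks had it), so peaks were ranked by the signal value. The p column was unset and not used. Whether the signal value is scaled by depth was not recorded, so replicates were compared by rank, by overlap and by correlation over peaks, and not by the size of the signal. The lists of single replicates and the pooled list each ended at 30000 peaks, so their lowest peaks reflect a limit on length and not a threshold. The lowest −log10 q was 0.262 in the pooled list and 0.0776, 0.458 and 0.456 in replicates 1, 2 and 3. Their weakest peaks therefore had little support by the deposited q value. The IDR list equalled the 9789 strongest peaks of the pooled list. How the list was cut is not recorded, so single peaks in it cannot be taken as each tested for repeatability. It held 196 intervals listed more than once with different summits, which were kept. Depth per replicate is unknown, and intervals given for shares cover counting error only. A list cannot show absence of the protein, only that no peak was listed.

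Annotation was Ensembl release 115 for the same assembly (18277 genes without transposable elements, 24111 transcript starts, 137547960 assembled bases on 2L, 2R, 3L, 3R, 4, X and Y), and the sequence was that of RefSeq. All peak ends lay within the chromosome lengths. Each summit was put in the first class that held it, in the order promoter (within 500 bp of a transcript start), 5' UTR, 3' UTR, coding exon, other exon, intron and intergenic, and the share of summits was tested against the share of bases with an exact binomial test. Arms were tested in the same way. A gene was counted as bound when an IDR summit lay within 500 bp of one of its starts, and the members of 26 gene lists were compared with all other protein-coding genes (all genes for the 2 lists of small RNAs) by Fisher's exact test. Symbols in older use were looked up by synonym, and SA, nos and phm, which could not be resolved to 1 gene, were left out. A summit between 2 neighbouring starts counts for both genes, so genes in a list are not independent of their neighbours.

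Occurrence of 11 known sequences, matched exactly to a consensus on either strand, was compared between the bases within 50 bp of a summit and a window of the same size at 300 bp to 1 random side with an exact McNemar test. For 8-base sequences, 10 were taken on 2L and 3L by the same test and tested again on 2R, 3R and X. Differences in log2 signal were tested with 100000 permutations. Overlap of replicates used their 9789 strongest peaks, with 100 random placements. Tests were two-sided, p was adjusted within each family by the Benjamini-Hochberg method (7 classes, 7 arms, 26 lists, 11 sequences, 10 sequences of 8 bases), and p under 1e-300 is printed as 1e-300. For zero counts the upper limit was 3 counts for the lists and the exact 95% interval for the Y.

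The genes named were set by a rule fixed before the data were examined: CG2712, the 25 strongest IDR peaks with the gene of the nearest start, up to 4 members of each list with the strongest promoter peaks, and all bound members where 5 or fewer had one. Some members that the rule names are not reported here. The gene lists, sequences, tests and most alternatives were also fixed before the data were examined. The alternatives fixed then were fewer or better replicated peaks, leaving out each replicate, other promoter windows, starts, backgrounds, flanks and overlap rules. Chosen after seeing the data were 1 peak per interval, comparison with positions or windows of matched GC content (10 positions per peak, 1 window per peak), the whole pooled list for the gene lists, and the tests of the closing section, 3 of which were set out before their results were seen. Peaks on sequences other than the 7 chromosomes were left out of the comparisons.

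Python 3.11.15 was used with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The tests were tried on simulated data. Of 20 sets of 5000 random positions, 0 passed the promoter test, and a planted promoter share of 48.0% was recovered as 48.4%. Random gene sets gave 1 call in 520 list tests over 18277 genes, and a planted list was called together with 1 other. Those genes were drawn singly, so summits shared by neighbouring genes were not built in, unlike in the data. How often the list tests call clustered genes wrongly was therefore not tried. Random windows gave 0 calls in 220 sequence tests, and an 8-base sequence planted in 122 of 4000 windows was ranked 1 in discovery. These windows were placed at random, so no gap in GC content from their flanks was built in, unlike at the peaks. Calls that follow from such a gap were not tried. The permutation test called 45 of 1000 sets with no difference.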

Results

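Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos of mixed sex, aged 0 to 16 hours, from a fly line that carries CG2712 fused at its C terminus to green fluorescent protein (GFP). An antibody against GFP pulled down the tagged protein with the DNA it was attached to, so that the peaks mark places where the tagged protein was found across the tissues and ages in the collection. CG2712 (FBgn0024975) lies on chromosome X from 2732469 to 2734402 (build dm6, plus strand), and its annotated protein of 501 amino acids has 7 matches to the spacing of the C2H2 zinc finger, a fold that often contacts DNA. There was 1 group of 3 biological replicates and no second condition, so the comparisons are between replicates, between peaks and the genome, and between sets of genes. Each replicate list and the list called on the replicates together held 30000 peaks, a length set by a limit. The list past the irreproducible discovery rate (IDR), a measure of how well peak ranks repeat between replicates, held 9789 peaks with a median width of 361 bp (106 to 1914) that merged into 9282 regions covering 3166223 bp. The signal values at these peaks, the authors' own, ran from 206.2 to 40613 with a median of 410.9. Read totals were not given in the sources used here, so the depth behind each list is unknown.

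The strongest places of CG2712 occupancy were starts of protein-coding genes with varied functions. The peak with the highest signal lay 60 bp from the start of CG2017 (3R, 5861661 to 5863004, signal 40613), and the next lay 52 bp from the start of CG4238 (2L, 2009213 to 2010478, signal 26225) and 41 bp from the start of Tbc1d8-9 (3L, 21343239 to 21344272, signal 23757). ATPsynB, a subunit of the mitochondrial ATP synthase, followed with a summit 11 bp from its start (3L, 9729509 to 9730535, signal 21679), then CG4282 (1 bp; 2R, 16321724 to 16322627, signal 19076), hrg (86 bp; 2R, 19668927 to 19670768, signal 18136) and CG30392 (50 bp; 2R, 21291747 to 21292773, signal 14365). The summit of the CG2017 peak had rank 1 in all 3 replicates, CG4238 rank 2 and Tbc1d8-9 rank 3.

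Of the 25 strongest IDR peaks, 22 had their summit in a promoter (within 500 bp of an annotated start) and 3 in an intron. The other promoter summits were nearest to px (rank 8), the ATP synthase subunit gene ATPsynCF6 (rank 11), SCCRO3 (12), the mitochondrial ribosomal protein gene mRpS10 (13), Pus7 (14), the vacuolar proton pump subunit gene Vha44 (15), CG18549 (16), Fkbp14 (17), the Polycomb group gene ph-p (18), Ugalt (19), ZnT63C (20), CG14100 (21), Chro (22), which encodes a chromatin protein of interbands, CG11309 (24) and msi (25). The intronic summits lay in ush (rank 9; 2L, 480540 to 481394, 1369 bp from the start of cbt), in CG11050 (rank 10; 2L, 6612375 to 6612998, 1022 bp from its start) and in Trl, which encodes the GAGA factor (rank 23; 3L, 14759224 to 14759800, 1538 bp from the start of CG42507). All 25 were within the 100 strongest peaks of every replicate, with lowest ranks of 52, 46 and 29 in replicates 1, 2 and 3, and 18 were within the 25 strongest of all 3. Together they held 4.74% of the summed signal of the IDR list, and the strongest was 98.8 times the median.

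**Figure D1:**
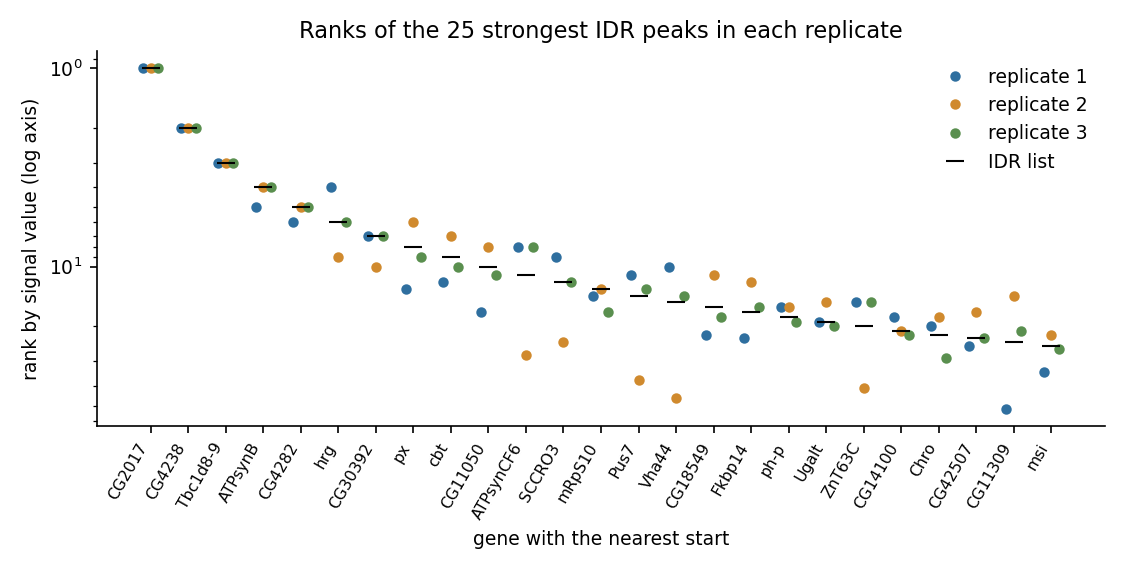
Rank by signal value (log axis, strongest at the top) of the 25 strongest IDR peaks, named by the gene with the nearest start; points are the 3 replicates and the bar is the IDR list. CG2017, CG4238 and Tbc1d8-9 hold ranks 1, 2 and 3 in all 3 replicates, and the lowest rank is 52, at CG11309 in replicate 1.

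Most of the same places were found again in each biological replicate. Of the 9789 IDR peaks, 9070 (92.7%) had a peak in all 3 replicate lists, and 6921 (70.7%) overlapped one of the 9789 strongest peaks of all 3. Among those strongest peaks, an IDR peak was found again in 85.8% of cases in replicate 1 (exact 95% interval 85.1 to 86.5), 89.6% in replicate 2 (89.0 to 90.2) and 86.7% in replicate 3 (86.0 to 87.4), a mean of 87.4% ± 2.01 (SD, n = 3). The IDR list was exactly the 9789 strongest peaks of the pooled list, so it was made from these replicates and its recovery in them is not independent of them.

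Set against each other, the 9789 strongest peaks of 2 replicates shared 79.7% (replicates 1 and 2), 77.8% (1 and 3) and 83.6% (2 and 3) of their peaks by at least 1 bp, a mean of 80.4% ± 2.93 (SD over 3 pairs). Random placement of peaks of the same widths on the same chromosomes gave 4.83%, and 5.50% at most in 100 placements of each pair. Across IDR peaks, Spearman's rho of the signal values was 0.814, 0.813 and 0.848 for the same pairs (mean 0.825 ± 0.020). Pearson's r of the log2 values averaged 0.861 ± 0.027. These are correlations across peaks, which are not independent replicates. The mean share fell to 63.6% when 50% of both peaks had to overlap.

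CG2712 peaks were concentrated at gene starts and nearly missing from coding sequence. Promoters held 4516 of 9789 summits, 46.1% (exact 95% interval 45.1 to 47.1), against 13.3% of assembled bases, a 3.48-fold excess. The 9789 strongest peaks of the replicates gave 44.5%, 45.7% and 49.9% (mean 46.7% ± 2.82, SD, n = 3). Coding exons outside promoters held 15 summits, 0.153% (0.0858 to 0.253) against 12.8% of bases. Introns took 34.0% of summits (39.1% of bases, ratio 0.869), intergenic DNA 17.6% (28.3%, ratio 0.622), 3' UTRs 0.827% (4.92%, ratio 0.168) and 5' UTRs outside promoters 0.429% (0.758%, ratio 0.566). Exons of other transcripts were at 0.868% against 0.821% of bases.

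Each class but the exons of other transcripts differed from its share of bases by a two-sided exact binomial test (adjusted p from 8.1e-05 for 5' UTRs down to 1e-300, the smallest value printed here, for promoters and coding exons), and the exons of other transcripts did not (adjusted p = 0.575; without replicate 2 they turned to a ratio of 0.987, exact p = 1). In all of these classes the replicate mean lay within 2 SD of the IDR value. The promoter excess depended on the window, at 5.15-fold within 250 bp of a start and 2.39-fold within 1000 bp. The call for 5' UTRs ended against random positions matched on GC content over 50 and over 200 bp either side (ratio 0.794, adjusted exact p = 0.172). That comparison was chosen after seeing the data.

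**Figure D2:**
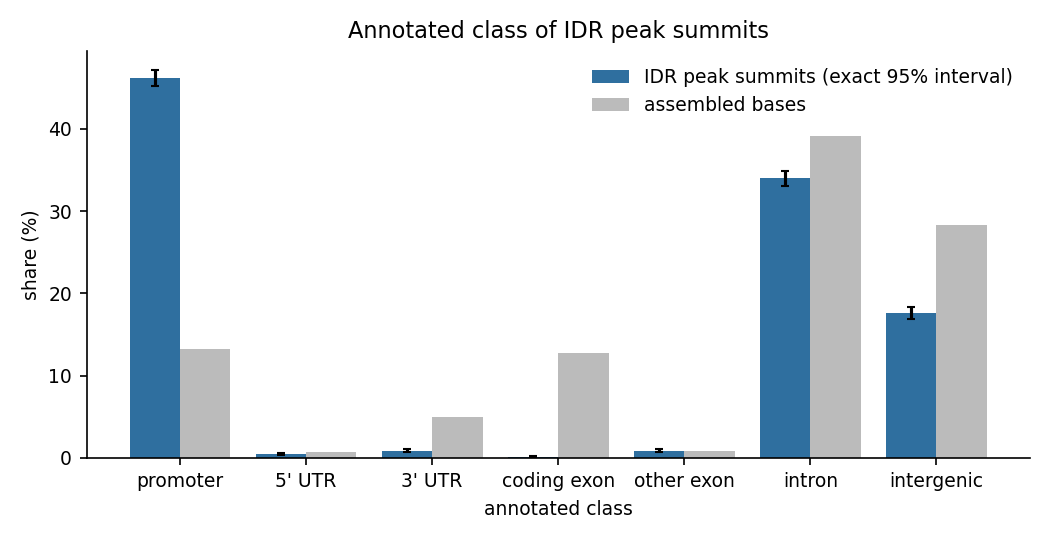
Share of the 9789 IDR peak summits (blue, with exact 95% intervals) and of assembled bases (grey) in each annotated class, in percent. Promoters hold 46.1% of summits and 13.3% of bases, and coding exons outside promoters hold 0.153% of summits and 12.8% of bases.

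Stronger peaks lay at promoters somewhat more often than weaker ones. With the IDR peaks split by signal into 10 groups of equal size, promoters held 56.6% of the strongest group and 39.9% of the weakest. The groups between did not fall in order (43.0% in the third and 50.3% in the sixth). Mean log2 signal was 9.0 at the 4516 promoter peaks and 8.87 at the 5273 others, a difference of 0.13 (two-sided permutation test, p = 1e-05, the smallest that 100000 permutations can give). With each replicate's own signal the difference was 0.33, 0.06 and 0.24 (mean 0.21 ± 0.14, SD, n = 3), higher at promoters in 3 of 3 replicates, with permutation p of 1e-05, 0.00439 and 1e-05. With the log2 signal averaged over 2 replicates, the difference was 0.30 without replicate 2 and 0.21 without replicate 3. These values are to be set against the replicate mean of 0.21, and not against the 0.13 of the pooled signal.

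All the major chromosome arms carried CG2712 peaks, and the dot chromosome 4 and the Y stood apart. Chromosome 4, a small and largely heterochromatic chromosome, had 53 peaks, 0.552 of the number its length would give (adjusted p = 5.1e-06, exact binomial test). The Y, also heterochromatic, had 0 of 9789, which allows a share of up to 0.0377%, against 2.67% of the assembled length. Of the assembled Y, 257633 bases are unresolved, and how far reads can be assigned to the rest was not examined. The 0 therefore does not show that the protein avoids the Y. By the same exact test, arms 3L (1.11-fold, adjusted p = 1.1e-07), X (1.08-fold, 0.000893) and 2L (1.07-fold, 0.00155) were above and 2R (0.935-fold, 0.00264) below the share of their length, and 3R did not pass the test (0.975-fold, 0.185). Counting only promoter peaks against promoter bases, the Y alone differed (adjusted exact p = 9.8e-12), and chromosome 4 had 34 peaks (0.949-fold, adjusted p = 1). The shortage on chromosome 4 over all peaks was over 1.5 times deeper without replicate 1 (0.354-fold), in the upper part of the IDR list by signal (0.313-fold) and in peaks among the strongest of all 3 replicates (0.339-fold). The excess on X was not found in that upper part (0.977-fold, adjusted exact p = 0.549). Without replicate 1 neither X (1.03-fold, 0.349) nor 2R (0.951-fold, 0.0566) passed the exact test.

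At least 1 IDR summit lay within 500 bp of a start for 4973 of 13968 protein-coding genes (35.6%). Lists of genes for ribosomal proteins, replication, the proteasome, translation factors and the respiratory chain had promoter peaks more often than other genes. The cytosolic ribosomal protein genes led with 80 of 92 (87.0%, odds ratio 12.2), for example RpL34b (signal 2470, rank 302), RpS3 (1807, rank 566) and RpS27 (1733, rank 611). Mitochondrial ribosomal protein genes had 50 of 73 (68.5%, odds ratio 3.96), among them mRpS10 (8396, rank 13), mRpS23 (6168, rank 31), mRpL41 (5764, rank 38) and mRpL23 (4022, rank 97). Genes of DNA replication and the cell cycle had 22 of 30 (73.3%, odds ratio 4.99), including RnrS (1809), a subunit of ribonucleotide reductase, the E2F partner Dp (1344), the mitotic kinase gene aurA (1048) and E2f1 (996.8). Without replicate 2 the odds ratio fell over 1.5 times for cytosolic ribosomal proteins (7.98) and for replication and the cell cycle (3.24). In peaks among the strongest of all 3 replicates, which keep replicate 2, it was 8.01 and 3.19. The fall therefore cannot be credited to leaving out replicate 2. In the upper part of the IDR list by signal it was 5.55 for the first, and 2.23 for the second, which no longer passed (adjusted exact p = 0.0927).

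Proteasome subunit genes had 27 of 48 (56.2%, odds ratio 2.33; Rpn3 1268, Prosbeta2 991.1, Rpn6 958.8, Rpn5 886.2). Translation factors had 29 of 53 (54.7%, odds ratio 2.19; eIF4EHP 4687, eIF6 2736, eEF1gamma 1445, eRF3 1421), and subunits of the respiratory chain and ATP synthase 43 of 84 (51.2%, odds ratio 1.90; ATPsynB 21679, ATPsynCF6 9887, ND-MWFE 1578, ND-ASHI 1436). The adjusted p, by Fisher's exact test (two-sided) over the 26 lists, was 2.4e-23 for cytosolic and 5.0e-08 for mitochondrial ribosomal proteins, and 8.7e-05 for replication and the cell cycle. It was 0.00866 for both the proteasome and the respiratory chain, and 0.0115 for translation factors. Replicate means of the share were 84.4% ± 1.66, 68.0% ± 5.54, 71.1% ± 3.85, 54.2% ± 3.61, 53.6% ± 3.15 and 57.9% ± 2.88 (SD, n = 3) in that order of lists. Among isolated genes, those over 1 kb from any other gene's start, mitochondrial ribosomal proteins (odds ratio 2.27, adjusted exact p = 0.328), translation factors (2.52, 0.120), the proteasome (2.08, 0.273) and the respiratory chain (1.45, 0.469) no longer passed the test. Without replicate 1 the proteasome (1.86, adjusted exact p = 0.0773), and without replicate 3 translation factors (1.83, 0.0592), did not pass. In the upper part of the IDR list by signal the proteasome (1.585, adjusted exact p = 0.234) and the respiratory chain (1.63, 0.0927) did not pass. Nor did the proteasome within 1000 bp of a start (1.97, adjusted exact p = 0.0509). In the whole pooled list of 30000 peaks, chosen after seeing the data, the proteasome (1.58, adjusted exact p = 0.202) and translation factors (1.85, 0.0618) did not pass. In the whole lists of replicates 1, 2 and 3 translation factors passed (2.39, 3.01 and 2.36, adjusted exact p = 0.00748, 0.000803 and 0.00681). The proteasome passed in none of these.

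Polycomb and trithorax group genes and insulator protein genes also had frequent promoter peaks. The Polycomb and trithorax group, which keeps developmental genes silent or active, had them in 19 of 23 (82.6%, odds ratio 8.62, adjusted p = 1.6e-05, Fisher's exact test), with ph-p (signal 7735, rank 18), brm (3813, rank 113), E(z) (3132, rank 180) and Sfmbt (886.7, rank 1802) the strongest. Insulator and architectural protein genes had 14 of 19 (73.7%, odds ratio 5.08, adjusted p = 0.00272, Fisher's exact test), with Chro (7264, rank 22), Cp190 (3829, rank 111), M1BP (1901, rank 517) and Nup98-96 (1304, rank 1000). Replicate means were 84.1% ± 2.51 and 84.2% ± 9.12 (SD, n = 3). The size of the Polycomb and trithorax odds ratio was unstable, at 5.46, 5.665 and 4.85 without replicates 1, 2 and 3 and 3.53 in the upper part of the IDR list by signal, and it passed the exact test each time. The insulator list did not pass among isolated genes (odds ratio 3.63, adjusted exact p = 0.477).

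Chemosensory receptor genes and Cpr cuticle protein genes rarely had a promoter peak. Of 180 chemosensory receptor genes, 2 had a promoter peak (1.11%, odds ratio 0.0199, adjusted p = 4.1e-30, Fisher's exact test), Ir67c (signal 238.0, rank 8610) and Gr63a (228.2, rank 8940). Of 70 Cpr cuticle protein genes, 2 did (2.86%, odds ratio 0.0528, adjusted exact p = 2.0e-10), Cpr67Fa1 (329.9, rank 6261) and Cpr65Ea (283.2, rank 7336). Without replicate 1 the odds ratio of the Cpr list was 0.0343, and without replicate 1 or 3 that of the receptors was 0. No peak lay at any of the 111 replication-dependent histone genes (adjusted exact p = 4.8e-21), and a count of 0 allows up to 2.70%. These genes stand in near-identical copies, and 1.41% of 50-base stretches around their starts occurred once in the assembled arms. Chorion (eggshell) genes had 0 of 9 (adjusted p = 0.0583, Fisher's exact test), and the same count passed within 1000 bp (0.0309) and in the whole pooled list (0.00786). Transfer RNA genes had an IDR summit at 50 of 295 (16.9%, odds ratio 0.473, adjusted exact p = 1.2e-06, at 33 distinct peaks). The tRNA odds ratio was 0.227 without replicate 2 and 0.210 without replicate 3, and the share varied widely between replicates (mean 19% ± 9.87, SD, n = 3). The lower share was not found in the whole pooled list, chosen after seeing the data. There 192 of 295 tRNA genes had a summit (65.1% against 44.1% of other genes, odds ratio 2.37, adjusted exact p = 3.0e-12). In the whole replicate lists 123, 192 and 197 did. The share was above that of other genes in replicates 2 (odds ratio 2.24, adjusted exact p = 1.3e-10) and 3 (2.32, 1.7e-11). In replicate 1 the share did not pass the test (41.7% against 43.9%, odds ratio 0.915, adjusted exact p = 0.565). Distinct peaks were not counted in the whole lists, where tRNA genes can also share a peak. Those lists reach down to peaks with little support by the deposited q value. The snoRNA and snRNA genes had 32 of 306 (10.5%, odds ratio 0.269, adjusted exact p = 2.2e-15, at 27 distinct peaks).

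The strongest peaks near small RNA genes were those at tRNA:Gln-CTG-2-3 (signal 26225, the peak of rank 2 that was nearer to the start of CG4238), tRNA:Tyr-GTA-1-8 (3938), tRNA:Gln-TTG-2-1 (1635) and tRNA:Gly-GCC-1-9 (913.7). Among snoRNA genes they were at snoRNA:Or-aca5 and snoRNA:Psi28S-2949, which shared 1 peak (1678) and snoRNA:Or-ACA6 (839.5). The lower share of the snoRNA and snRNA list did not pass the test within 1000 bp of a start (odds ratio 0.795, adjusted exact p = 0.114) or among isolated genes (0.586, 0.342).

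**Figure D3:**
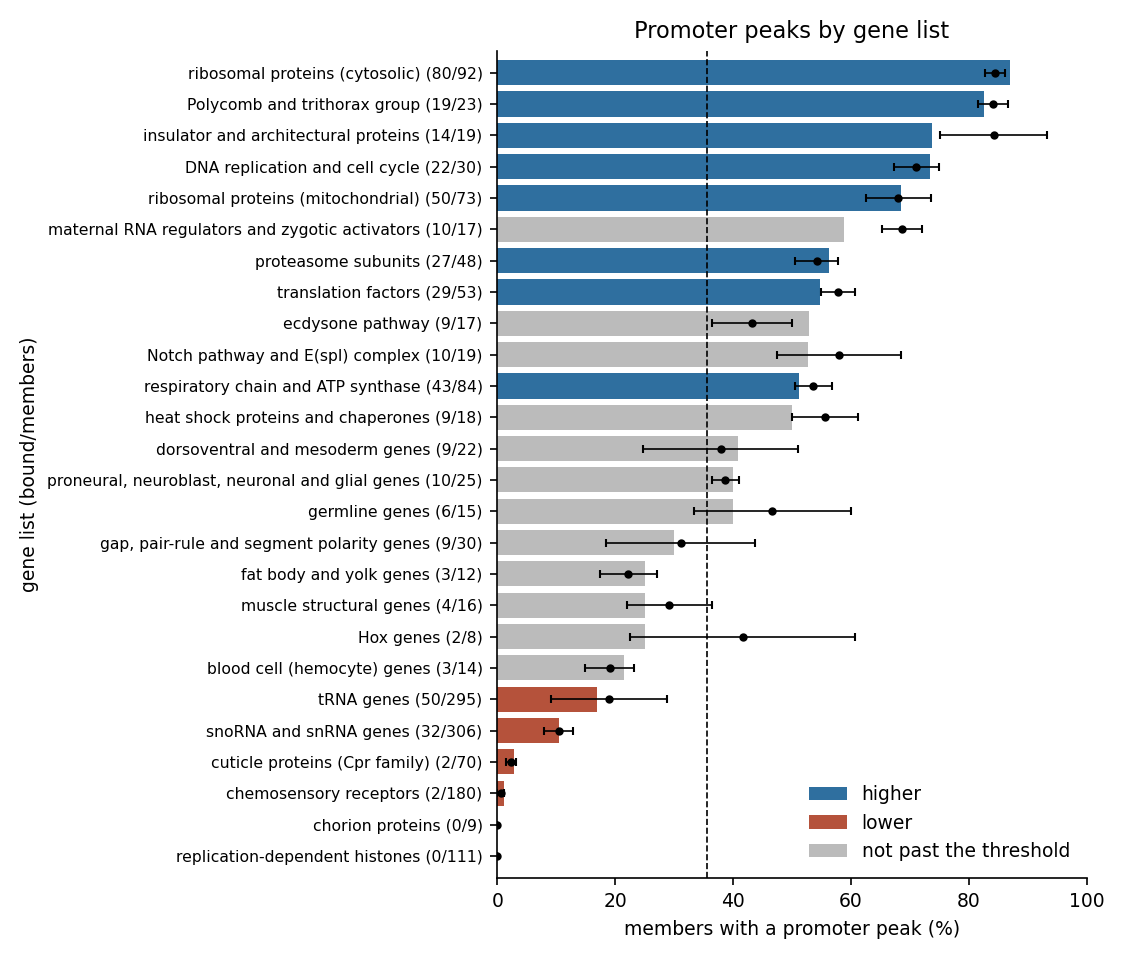
Percent of the members of each of 26 gene lists with an IDR summit within 500 bp of a start (bars, coloured by the direction of lists past an adjusted p of 0.05 in Fisher's exact test), with the mean and SD of the 3 replicates (points). The dashed line is the 35.6% of all protein-coding genes; cytosolic ribosomal proteins reach 87.0% and chemosensory receptors 1.11%.

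No list of patterning genes or tissue markers passed the test in the IDR list. Leaving aside the chorion genes given above (0 of 9), their shares ran from 21.4% to 58.8%. In the whole pooled list, chosen after seeing the data, dorsoventral and mesoderm genes (odds ratio 3.51, adjusted exact p = 0.0178) and the Notch list (5.51, 0.00487) passed, and the Hox (1.03) and segmentation (1.35) odds ratios turned. In the whole replicate lists the Notch list passed each time. Dorsoventral genes passed in replicate 2 (4.39, adjusted exact p = 0.00773) and not in replicates 1 (1.81, 0.279) or 3 (1.99, 0.181). All of the whole lists include peaks with little support by the deposited q value. The gene lists are short, so a difference from other genes is not ruled out. Hox genes had 2 of 8 (25%, exact 95% interval 3.19 to 65.1, adjusted p = 0.749, Fisher's exact test, as for all lists here), Antp (signal 1015) and lab (394.9). Gap, pair-rule and segment polarity genes had 9 of 30 (30.0%, 0.677), with nkd (2183), bcd (873.4), hry (568.0) and ptc (406.1). Their odds ratio of 0.775 was 0.493 without replicate 2 and 0.515 without replicate 3, and turned among isolated genes (1.71). The dorsoventral and mesoderm genes had 9 of 22 (40.9%, 0.735), with tin (2728), htl (1128), rho (440.3) and Mef2 (314.0). Their odds ratio of 1.25 turned without replicate 2 (0.390) and without replicate 3 (0.572), neither past the exact test. The Notch pathway and E(spl) complex had 10 of 19 (52.6%, 0.243), with E(spl)m7-HLH (3159), numb (2863), E(spl)mdelta-HLH (2784) and E(spl)m3-HLH (2409). Proneural, neuroblast, neuronal and glial genes had 10 of 25 (40%, 0.735), with elav (4342, rank 80), a marker of neurons, far above Nrt (985.1), fne (467.4) and Nrg (400.1). Their odds ratio of 1.21 turned in the upper part of the IDR list by signal (0.524) and within 250 bp (0.905), neither past the exact test.

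Among markers of other cell types, muscle structural genes had 4 of 16 (25%, adjusted p = 0.578, Fisher's exact test for each list here), namely Msp300 (1845), sls (1405), Act87E (1135) and Tm1 (1092). The muscle odds ratio of 0.603 turned in the upper part of the IDR list by signal (1.28) and in the whole pooled list (2.27), and was 0.155 within 250 bp and 0.329 among isolated genes, none past the exact test. In the whole pooled list the blood cell (1.37) and germline (0.902) odds ratios also turned without passing, and the maternal and zygotic list (3.35, adjusted exact p = 0.0496) passed. That list also passed in the whole lists of replicates 1 (4.82, adjusted exact p = 0.0135) and 3 (4.34, 0.0237), and not of replicate 2 (2.34, 0.187). Blood cell genes had 3 of 14 (21.4%, 0.552), namely ush (397.1), crq (320.4) and srp (228.1), and fat body and yolk genes 3 of 12 (25%, 0.677), namely Adh (834.8), apolpp (311.9) and FASN1 (241.8). The odds ratio of the fat body and yolk list fell from 0.603 to 0.216 without replicate 1, not past the exact test. Germline genes had 6 of 15 (40%, 0.789), with Tdrd3 (1431), gcl (953.1), spn-E (932.9) and vas (833.3) the strongest. Maternal RNA regulators and zygotic activators had 10 of 17 (58.8%, 0.125), with the promoter peak of Trl (851.8), grh (762.8), smg (704.6) and plu (666.5). The ecdysone pathway had 9 of 17 (52.9%, 0.310), with Eip75B (2840), usp (638.7), EcR (414.1) and shd (364.5), and its odds ratio of 2.04 turned without replicate 3 (0.793, not past the exact test). The heat shock proteins and chaperones had 9 of 18 (50%, 0.321), with Hsp27 (3639), Hsc70-5 (1427), Hsp26 (1268) and Hsp83 (1130).

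A CG2712 peak lay between the start of its own gene and that of the neighbour ttm50, and was nearer to ttm50. The peak on chromosome X from 2732131 to 2732552 had its summit at 2732316, 153 bp from the start of CG2712 and 126 bp from the start of ttm50, with a signal of 1614 and rank 697 in the IDR list. It had ranks 540, 782 and 700 in replicates 1, 2 and 3. Weaker summits 52, 25 and 46 bp from the start of CG2712 had ranks 29692, 5267 and 7659 in those lists, and none of them was in the IDR list. Within 10 kb of CG2712 there were 4 IDR peaks, the others near crm and Syx4 (2 peaks), against 1.56 at the mean density of the list. The replicate lists held 4, 9 and 11 peaks there against 4.78 expected in each, so replicate 1 had no excess, and it had no peak near crm. No test was made of 1 locus. The flies are transgenic for the tagged gene, and whether reads from the transgene contribute to this peak is not recorded in the sources used here.

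Summits held several known sequences of promoter and insulator factors more often than their flanks. The DNA replication-related element (DRE, bound by Dref and BEAF-32) was within 50 bp of 2.57% of summits against 0.480% of flanks 300 bp away (5.36-fold). The M1BP sequence Motif 1 was in 1.71% against 0.470% (3.63-fold), the insulator sequence of CTCF in 1.23% against 0.276% (4.44-fold) and that of Su(Hw) in 2.54% against 1.93% (1.32-fold). The GAGA repeat of Trl and CLAMP (0.552% against 1.25%), the Zelda site (0.347% against 0.633%) and the E-box (0.684% against 1.43%) were less frequent at summits than in flanks. The E-box was searched for only as CACGTG, so its values do not cover other E-box forms. The TATA box (25.2% against 9.85%), the homeodomain core (11.2% against 5.12%) and the GATA site (16.9% against 11.5%) were more frequent. The initiator (8.60% against 9.27%, 0.928-fold) did not pass the test (adjusted exact p = 0.109), but did without replicate 2 (0.854-fold, 0.00376) or without replicate 3 (0.847-fold, 0.00199). The GAGA ratio of 0.443 was 0.278 without replicate 2.

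In two-sided exact McNemar tests over the 9789 summit and flank pairs the other adjusted p ran from 9.2e-175 (TATA box) to 0.00559 (Zelda). The share at summits averaged 2.40% ± 0.223 for DRE, 1.79% ± 0.312 for Motif 1 and 1.22% ± 0.133 for CTCF over the replicates (SD, n = 3). The size of the DRE, Motif 1 and CTCF excesses depended on the comparison, although each stayed past the exact test. In the upper part of the IDR list by signal DRE was 3.46-fold and Motif 1 1.96-fold. With flanks 1000 bp away DRE was 8.13-fold, Motif 1 6.19-fold and CTCF 8.57-fold, and with windows of 100 bp either side CTCF was 2.87-fold. Against the same summit windows read backwards, which have the same base composition, DRE (7.88-fold), Motif 1 (3.09), CTCF (24.0) and Su(Hw) (2.77) stayed above and the E-box (0.300) below. In that comparison the TATA box (0.698) and GATA (0.937, adjusted exact p = 0.0501) turned, the initiator (1.18) rose past the test, and the homeodomain core (1.02, 0.533) and Zelda (0.723, 0.194) lost it. The GAGA repeat reads nearly alike backwards, so this comparison says nothing about it. Against random windows of the same GC content, chosen after seeing the data, Motif 1 (12.9-fold) and CTCF (10.9-fold) were further above, and GAGA was above (1.86, adjusted exact p = 0.0177) and the TATA box fell from 2.56-fold to 1.07-fold, which still passed (0.0174). There the E-box (1.08, 0.725), Zelda (1.79, 0.0821), the initiator (1.095, 0.0821) and the homeodomain core (0.964, 0.389) turned without passing, and Su(Hw) (1.15, 0.179) and GATA (1.07, 0.0821) did not pass.

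The 8-base sequences most enriched at summits over flanks were runs of A and T. All 10 found on arms 2L and 3L, led by AAAAATAT and TATTTAAA, held no G or C, and on the held-out arms 2R, 3R and X all 10 were again more frequent at the 5716 summits than in flanks, by 2.73-fold to 4.38-fold (largest adjusted p = 5.6e-21, exact McNemar test). GC content, examined after these were seen, was 32.7% on average within 50 bp of summits (SD 9.92 over peaks), 44.1% in flanks and 42.1% over the assembled arms. It was 34.8% at promoter summits and 30.9% at others, lower than in the flank at 7575 of 9789 peaks (77.4%), and 33.1% ± 1.15 over the replicates (SD, n = 3). The strongest of the 10 groups of peaks by signal was at 27.9% and the weakest at 36%.

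**Figure D4:**
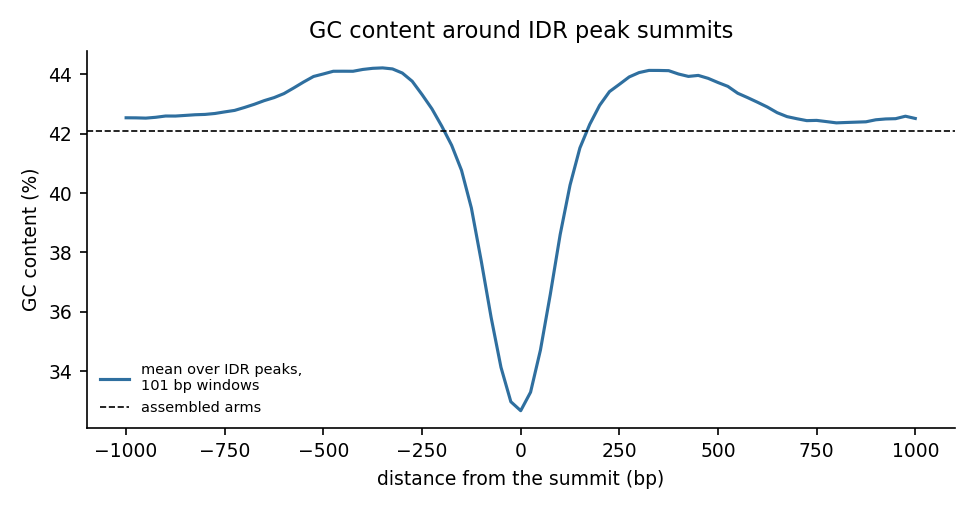
Mean GC content (percent) of windows of 50 bp either side at distances of up to 1000 bp from the summits of 9789 IDR peaks (line), with the value over the assembled arms (dashed). The line falls to 32.7% at the summit against 42.1% over the arms; the vertical axis does not start at 0.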

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

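The test of copy number below was set out before its result was seen; those on base composition were chosen after the peaks and their GC content had been examined.

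Replicate 3 held 23 peaks on the mitochondrial genome, the strongest at rank 16 of its list, and these lie outside the chromosomes compared in the report. The other 4 lists held 0 such peaks. With no control list analysed, the 23 were singled out because they exceed the 3 counts that a count of 0 allows. Whether mitochondrial peaks were filtered from the other lists is not recorded in the sources used here, and if they were, their 0 is no measurement and the comparison says nothing.

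The AT-rich summits and their near absence from coding exons go together, since coding DNA is rich in GC. Random positions on the same arms, matched to each summit on GC content over 50 and over 200 bp either side, fell in promoters in 14.1% of cases, far below the interval of the peaks (45.1 to 47.1%), so base composition alone does not place the peaks at promoters. The same positions fell in coding exons in 3.53% of cases against 0.153% (0.0858 to 0.253) of summits, so it does not account for the whole shortage there either, although it took the expected share down from 12.8%. A preference of the libraries or the caller for AT-rich DNA could still contribute to the low GC content itself (median 30.7% over summit windows) and cannot be told apart from one of the protein, because no control list was analysed. No biological explanation was tested, since the design has 1 group.

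No list, including the 30000 peaks of each replicate and of the pool, had a summit within 500 bp of the start of any of the 111 replication-dependent histone genes. Only 1.41% of 50-base stretches around these starts occurred once in the assembled arms, against 98.9% at chemosensory receptor genes and 99.6% at cytosolic ribosomal protein genes. Sequence shared between the copies, to which reads cannot be assigned singly, may therefore account for the missing histone peaks, and the data do not show whether CG2712 is there. For chemosensory receptors, where 2 of 180 genes had an IDR summit, shared sequence is not an explanation.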

How the results depend on the processing

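The alternatives fixed before the data were examined were set against the values of the report, together with 1 peak per interval, positions or windows of matched GC content and the whole pooled list, which were chosen after seeing the data. Taking the 9789 strongest pooled peaks moved nothing, since they are the IDR list, and says nothing about stability. Under the other alternatives, 472 values kept their direction and side of the threshold or moved by less than the spread between replicates. The promoter excess stayed between 2.39-fold and 5.15-fold in all alternatives run. No paired analysis was possible because there is 1 group. Unknown depth limits what the weakest peaks show. Where a call ended, the cause was not tested. Fewer genes or peaks were tested with isolated genes, the upper part of the list and peaks among the strongest of all 3 replicates (6921). Leaving out replicate 1, 2 or 3 also left fewer peaks (7779, 7409 and 7651), so calls lost there cannot be credited to the replicate.

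In the upper part of the list by signal, X (0.977-fold) and 3R (1.01-fold) turned, as did the odds ratios of dorsoventral (0.606), neural (0.524), muscle (1.28) and ecdysone (0.823) genes, none past the exact test, and the odds ratios of the proteasome (1.585), the respiratory chain (1.63) and replication and the cell cycle (2.23) lost the threshold. Among isolated genes 7 lists passed; mitochondrial ribosomal proteins (2.27), translation factors (2.52), the proteasome (2.08), the respiratory chain (1.45), insulator proteins (3.63) and snoRNA and snRNA genes (0.586) did not, and segmentation genes turned (1.71). Within 1000 bp the proteasome (1.97) and snoRNA and snRNA genes (0.795) were lost and chorion genes (0) passed, and within 250 bp neural genes turned (0.905). In the whole pooled list of 30000 peaks tRNA genes turned past the test (2.37), Hox (1.03), segmentation (1.35), muscle (2.27), blood cell (1.37) and germline (0.902) genes turned without passing, translation factors (1.85) and the proteasome (1.58) lost the threshold, and dorsoventral (3.51), Notch (5.51), maternal and zygotic (3.35) and chorion (0) genes passed. With windows read backwards the TATA box (0.698), GATA (0.937) and initiator (1.18) turned, and Zelda (0.723) and the homeodomain core (1.02) were lost. GAGA (0.806) was lost too, but the repeat reads nearly alike backwards, so that value says nothing. With GC-matched windows 5 of 11 sequences passed; GAGA (1.86), Zelda (1.79), the E-box (1.08), the initiator (1.095) and the homeodomain core (0.964) turned, and Su(Hw) (1.15) and GATA (1.07) were lost. Against GC-matched positions (50 and 200 bp either side) 5' UTRs (0.794) were lost. In peaks found among the strongest of all 3 replicates the initiator passed (0.851), and dorsoventral (0.439) and ecdysone (0.856) genes turned.

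Leaving out 1 replicate gave 0.909 to 0.951 for 2R, 1.03 to 1.10 for X, 1.86 to 2.48 for the proteasome, 1.83 to 2.21 for translation factors and 0.847 to 0.922 for the initiator. Without replicate 1, 2R, X and the proteasome lost the threshold, as translation factors did without replicate 3, and the initiator passed without replicate 2 or 3. Turning in some of these without passing were other exons (0.987 to 1.07), dorsoventral genes (0.390 to 1.36) and ecdysone genes (0.793 to 2.12). The overlap between replicates ran from 77.8% to 83.6% and rho from 0.813 to 0.848. With 50% of both peaks the overlap was 63.6% and recovery of IDR peaks 71.1%, with summits within 100 bp 72.5% and 82.9%, and over whole lists the overlap was 68.5%.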

Other observations

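All tests in this part were chosen after the peaks had been examined, except those on repeat copies and on other places of the sequence in the genome, which were set out before their results were seen.

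Promoter summits lay mostly just upstream of a gene start, and genes that start back to back with another were bound at a higher rate than other genes. Among 4516 promoter summits, 3667 lay upstream of the nearest start, 838 downstream and 11 at it (81.4% upstream of the 4505 not at the start, exact 95% interval 80.2 to 82.5, exact binomial p = 1e-300 or less), with a median position of -94 bp and quartiles of -178 and -20 bp. Of 3815 protein-coding genes whose start lies within 500 bp of a start on the opposite strand pointing away, 2432 were bound (63.7%), against 2541 of 10153 others (25%, odds ratio 5.27, Fisher's exact test). Part of that excess comes from summits counted for both genes of a pair. With each summit given to the nearest start alone, 35.8% of the paired genes and 23.4% of the others were bound (odds ratio 1.82, p = 2.5e-47, Fisher's exact test).

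Promoter peaks and other peaks differed in 6 of 11 known sequences. DRE was in 5.29% of 4516 promoter summits and 0.247% of 5273 others (odds ratio 22.6, adjusted p = 1.8e-63), and Motif 1 in 3.37% and 0.284% (odds ratio 12.2, adjusted p = 1.6e-34, by Fisher's exact test as for each known sequence), and the E-box was also higher at promoters (1.06% and 0.360%, 7.6e-05). The TATA box (22.0% and 28.0%, adjusted exact p = 2.0e-11), GATA (14.7% and 18.9%, 1.1e-07) and the homeodomain core (10.3% and 12%, 0.0142) were lower there, and Su(Hw) (2.17% and 2.86%, 0.0525), CTCF (1.02% and 1.40%, 0.133), GAGA, Zelda and the initiator did not pass. Base composition may account for part of this, since the windows read backwards also differed for the TATA box (34.0% and 37.9%), GATA (15.8% and 20.1%) and Motif 1 (0.996% and 0.171%), but hardly for DRE (0.332% and 0.322%). When 8-base sequences were compared with the same windows read backwards, the 10 found at promoters on 2L and 3L all passed on 2R, 3R and X (9 of 10 found away from promoters did), among them DRE (TATCGATA, 5.54% against 0.407%), Motif 1 (GGTCACAC, 3.36% against 0.850%), CAACACTG (2.55% against 0.111%) and AACAGCTG (2.14% against 0.0739%). Several of the 10 at promoters are shifted copies of one another, such as ATCGATAG and TATCGATA, or ACAGCTGA and AACAGCTG. They are therefore fewer than 10 separate sequences. AACAGCTG holds CAGCTG and not CACGTG, the only form tested here as the E-box.

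All 7 strongest peaks, at CG2017, CG4238, Tbc1d8-9, ATPsynB, CG4282, hrg and CG30392, held ATTGTGAA with its centre within 23 bp of the summit, inside the longer form CYATTGTGAAYKG, and no flank of the 25 strongest did. Both forms were derived from these 7 peaks, the first as the only 8-base sequence that all of them share. Their presence in all 7 was therefore fixed in advance, and the contrast with the flanks of these 7 is no support. Chance alone is argued against by the ranks further down. The 8-base form was in 4 of 18 peaks of ranks 8 to 25 and 98 of 9764 beyond (Fisher's exact p = 3.0e-05). The longer form was in 1 and 8 (exact p = 0.0164, resting on 1 peak), and without its outermost base in 3 and 12 (exact p = 2.4e-06). These tests did not control base composition, which differs with peak strength. Of 10000 random windows matched in GC content to the 25 strongest summits, 0.57% held the 8-base form, against 22.2% of ranks 8 to 25. That difference was not tested. Copies of a repeat are argued against by the bases around the longer form. There no pair of the 7 peaks was alike at more than 41.0% of 100 bases without gaps (up to 45.0% when shuffled). However, 4 of the 7 summit windows held bases masked as repeats, up to 36.6% of a window. A candidate explanation, as a hypothesis, is that the tagged protein recognises this sequence. Whether it marks other places stays open: outside the 25 strongest peaks 8 of 37 places of the longer form lay in IDR peaks against 2 of 15 of its reversed form (Fisher's exact p = 0.704), and although a p above 0.05 had been set beforehand as evidence against, that reading was set aside after the value was seen, as so few places leave a 95% interval of the odds ratio of 0.293 to 19.4.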
